A study of Mus musculus with 3 samples.

How the data were processed

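The study addressed HDAC6 inhibition in the cognitive impairment that follows doxorubicin. Nuclei from frozen mouse hippocampus, isolated with Triton X-100, were sequenced with the 10x 3' version 3 chemistry. There were 3 libraries, each pooled from both hippocampi of 4 mice: control (no treatment), doxorubicin (a topoisomerase II poison used in chemotherapy), and doxorubicin plus ACY-1083 (an inhibitor of the deacetylase HDAC6). The labels give no dose, sex, strain or age.

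The deposited matrices hold raw UMI counts per gene and barcode, with no normalization. Per the file headers, Cell Ranger 4.0.0 made the control and doxorubicin matrices and Cell Ranger 5.0.0 made the doxorubicin plus ACY-1083 matrix, while the submitters' processing notes name Cell Ranger 6.0.0 and mm10 for each library. Whether reads in introns were counted is not given in the sources used here. The matrices hold 10909, 12221 and 12192 barcodes with 19175447, 21458785 and 62151258 UMIs (control, doxorubicin, doxorubicin plus ACY-1083), and the lowest barcode of each has 500 UMIs. Median UMIs per barcode were 1487, 1485 and 3912.5. Gene coordinates and intron lengths were taken from GENCODE vM21 (GRCm38), which matched 32158 of 32285 genes (99.61%) on Ensembl ID. Atp5pb, Aldoa, Ddit3, Clec7a and Mx1 were not found under those symbols and were not analysed here.

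Kept nuclei had at least 300 genes and under 5% mitochondrial UMIs, and Scrublet doublets, scored per library in scanpy 1.11.5, were removed. Doublets were 540 (4.95%), 244 (2.00%) and 466 (3.82%) of the barcodes, and 10367, 11976 and 11724 nuclei were kept (34067 in total). The 3 libraries were clustered together without integration (counts scaled to 10000 per nucleus and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). This gave 38 clusters, of which 16 had at least 90% and 15 at most 10% of their nuclei from the doxorubicin plus ACY-1083 library. Because the libraries parted in this way, each cluster was named on its own from marker lists, so names stand for likeness to those markers. Each cluster was compared with the other nuclei of the library that held most of it, with 20 CPM added before log2. It took the class with the highest mean log2 fold over at least 3 detected markers if that mean was at least 1 with an own marker among the 10 leading genes, or if 2 own markers were among them, unless another class had more. This rule named 30 clusters, left 6 unnamed and set 2 apart that had oligodendrocyte markers but over 3 times the median UMIs of the main oligodendrocyte cluster of their library. Classes with at least 100 kept nuclei in every library were compared, which held for 12 classes.

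UMIs were summed per library and class and divided by the class total to give CPM, the usual scaled count. Ratios are CPM ratios with 0.5 counts added before log2. Each CPM has an exact Poisson interval, each CPM ratio an exact Clopper-Pearson interval conditional on the sum, and each share an exact Clopper-Pearson interval, at 95%. These intervals cover counting error only. There was 1 library per group and no replicate, so no test between groups was made, no p-value is given, and the values describe the libraries. Where a class had no UMI of a gene in the library below the line, the fold is a bound computed from 3 UMIs over that class of that library.

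Genes were named by size. Eligible genes had at least 100 UMIs in the class in the higher library, were not mitochondrially encoded, ribosomal protein, hemoglobin, sex-linked marker or predicted genes or markers of another class, and had a CPM of at least 0.1 times that of their highest class. In the 8 classes that kept enough nuclei when each was thinned to 1000 UMIs, they also kept their direction there. They were ranked by the interval bound nearest to a ratio of 1, and the 2 highest and 2 lowest of each class were named. Genes whose bound passed 1.5 in doxorubicin against control and 1.5 the opposite way in doxorubicin plus ACY-1083 against doxorubicin were named as opposite, up to 2 per class, and Hdac6 was named in every library and class. Of 33 gene lists, the 2 members with the most extreme ratio were named. A list value is the median log2 ratio of its members with a class mean of at least 10 CPM, given for at least 3 members, with its percentile among 10000 random lists matched on mean expression. The expression difference is the median absolute log2 ratio over genes with a class mean of at least 100 CPM. It is set beside counting noise from a single simulated draw per class and library. It is also set beside random splits of the control or doxorubicin nuclei, each part with 0.5 of them. Separately, 100 simulated draws gave the counting intervals of summary values and list medians used for the alternatives. The composition distance is 0.5 times the summed absolute differences of class shares.

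The gene lists, marker lists, filters, comparisons, naming of genes and the alternatives in the closing section were chosen before the data were examined, except the following choices, which were made after the data were seen. The cluster naming rule was widened because the original form, a mean marker fold of at least 1 alone, left a CA1 cluster (mean 0.73) unnamed. The deep clusters were set apart. A set of 375 genes with at most 300 bp of intron (short-intron genes) was compared on its own, with each ratio centred on the median of the class. A floor of 150 short-intron UMIs per nucleus, picked after floors from 0 to 400 were viewed, was tried as an alternative, as were list percentiles among 2000 random lists matched on intron length too. Alternatives covered the filter on nuclei, doublets, thinning, separate clustering, resolution, TMM scaling, equal weight per nucleus and filters on low values.

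The ratios, their ranking and the list percentiles were tested on simulated data, Poisson counts drawn from the mean profile of the libraries compared, with 200 changed genes. In the doxorubicin against control design, 71.4% of genes changed 2-fold in dentate gyrus granule neurons and 80.9% in astrocytes had a bound past 1.5 in the right direction. In the doxorubicin plus ACY-1083 against doxorubicin design, 94.7% and 89.4% did. No unchanged gene had a bound past 1.5, though in granule neurons of the former design 30.9% had an interval excluding a ratio of 1. Over these 4 cases, 2.5% to 5.5% of unchanged lists of 20 genes fell outside the range holding 95% of random lists, and 95% to 100% of lists shifted by 0.3 on the log2 scale lay above it. The unchanged lists were random draws of independently simulated genes, so the share outside was close to fixed in advance. Lists whose members vary together were not simulated. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.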

Results

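Hdac6, the target of ACY-1083 (ENSMUSG00000031161, chromosome X, 7930120 to 7947889, GRCm38), had similar levels in the control and doxorubicin libraries, at 64.6 CPM (95% interval 60.9 to 68.4, 1160 UMIs) and 59.0 CPM (55.7 to 62.3, 1235 UMIs). In the doxorubicin plus ACY-1083 library it had 27.9 CPM (26.5 to 29.2, 1626 UMIs), a log2 ratio of -1.08 to doxorubicin, but 139 UMIs per 1000 nuclei against 103 in the doxorubicin library and 112 in control. CPM of that library cannot be set directly beside the others, because its counts follow intron length, as given further on. GABAergic neurons had the highest Hdac6 in each library, at 134, 105 and 49.5 CPM in the order control, doxorubicin, doxorubicin plus ACY-1083, and were 0.783-fold (0.635 to 0.965) in doxorubicin relative to control. Dentate gyrus granule neurons had 59.1, 51.9 and 27.8 CPM, CA1 pyramidal neurons 53.7, 52.0 and 26.9 CPM, and CA2/CA3 pyramidal neurons 59.1, 49.4 and 23.7 CPM. Subicular or cortical excitatory neurons had 68.0, 65.4 and 32.5 CPM, and thalamic or habenular neurons 102, 84.0 and 35.8 CPM. Oligodendrocytes had 32.0, 26.8 and 16.9 CPM, their precursor cells 48.5, 57.3 and 36.7 CPM, and astrocytes 36.0, 45.4 and 21.4 CPM. Fibroblast-like cells had 17.4, 24.1 and 14.96 CPM, and choroid plexus epithelium 45.7, 49.4 and 20.6 CPM. Microglia had 28.3, 72.5 and 18.0 CPM from 14, 43 and 18 UMIs, which made them 2.56-fold (1.38 to 5.07) higher in doxorubicin than in control.

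Granule neurons of the dentate gyrus were the most numerous named class of each library. Granule neurons were 24.4% (23.6 to 25.2), 22.996% (22.2 to 23.8) and 22.6% (21.8 to 23.3) of the kept nuclei of the control, doxorubicin and doxorubicin plus ACY-1083 libraries, and CA1 pyramidal neurons 14.7%, 13.8% and 13.9%. Oligodendrocytes were 6.79% (6.31 to 7.29), 7.71% (7.24 to 8.199) and 14.4% (13.8 to 15.05). Subicular or cortical excitatory neurons were 13.9% (13.3 to 14.6), 10.997% (10.4 to 11.6) and 3.74% (3.41 to 4.10), and thalamic or habenular neurons, from outside the hippocampus, 2.62%, 3.57% and 2.87%. CA2/CA3 pyramidal neurons were 5.30%, 4.53% and 7.19%, and GABAergic neurons 7.16%, 6.65% and 6.36%. Astrocytes were 9.20%, 10.1% and 8.42%, oligodendrocyte precursor cells 2.29%, 2.67% and 2.47%, and microglia 2.24%, 2.30% and 2.47%. Fibroblast-like cells were 1.69%, 1.76% and 2.21%, choroid plexus epithelium 0.965%, 1.23% and 1.03%, and unnamed clusters 5.69%, 8.43% and 9.10%. The composition distance was 6.77 percentage points between doxorubicin and control, 11.5 between doxorubicin plus ACY-1083 and doxorubicin, and 15.1 between doxorubicin plus ACY-1083 and control. Under alternatives the distance was 4.11 to 6.95 between doxorubicin and control and 10.8 to 27.7 between doxorubicin plus ACY-1083 and doxorubicin, in part from cluster naming.

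The subicular or cortical share was not separated from what was dissected or from cluster naming. Its nuclei lay in cluster 7 for control and doxorubicin but mostly in cluster 33 for doxorubicin plus ACY-1083. Unnamed clusters 28 and 32, with 534 and 146 nuclei of doxorubicin plus ACY-1083 alone, were led by Tshz2 and Fn1 respectively, which were also leading genes of cluster 7. At Leiden resolution 0.5 subicular or cortical neurons were 13.99%, 11.1% and 9.95%, and unnamed clusters 3.56% of doxorubicin plus ACY-1083. All barcodes had at least 500 UMIs, a floor that 9.17% of doxorubicin plus ACY-1083 nuclei came near (under 1000 UMIs) against 27.7% in control and 27.8% in doxorubicin, so the floor did not act alike on the libraries. With at least 175 short-intron UMIs per nucleus, oligodendrocytes were 3.87% (3.48 to 4.30), 4.12% (3.74 to 4.52) and 8.77% (8.204 to 9.37) of the nuclei, and with at least 300 they were 1.08%, 1.32% and 1.58%, with overlapping intervals. With at least 400 they were 0.824%, 1.05% and 0.569%, from 32, 54 and 27 nuclei. These floors rest largely on Malat1. It gave 4475711 of 5202400 short-intron UMIs in doxorubicin plus ACY-1083 and 4887460 of 5549460 in doxorubicin.

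The order of the libraries depended on the processing for several classes. CA1 neurons were 13.1%, 12.97% and 9.80% with doublets kept, and 18.9%, 18.1% and 14.9% with thinned nuclei. CA2/CA3 neurons were 9.30%, 9.70% and 7.12% with at least 600 genes per nucleus. With that filter astrocytes were 4.34%, 5.93% and 8.73%, and oligodendrocyte precursor cells 1.32%, 1.92% and 2.75%. Microglia were 1.65%, 1.69% and 1.18% with at least 150 short-intron UMIs per nucleus. Oligodendrocytes and subicular or cortical neurons kept the order, though not the size, of their shares in doxorubicin and doxorubicin plus ACY-1083 under the 6 alternatives for which the shares of each class were computed, while at the floor of 400 short-intron UMIs oligodendrocytes did not.

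**Figure D1:**
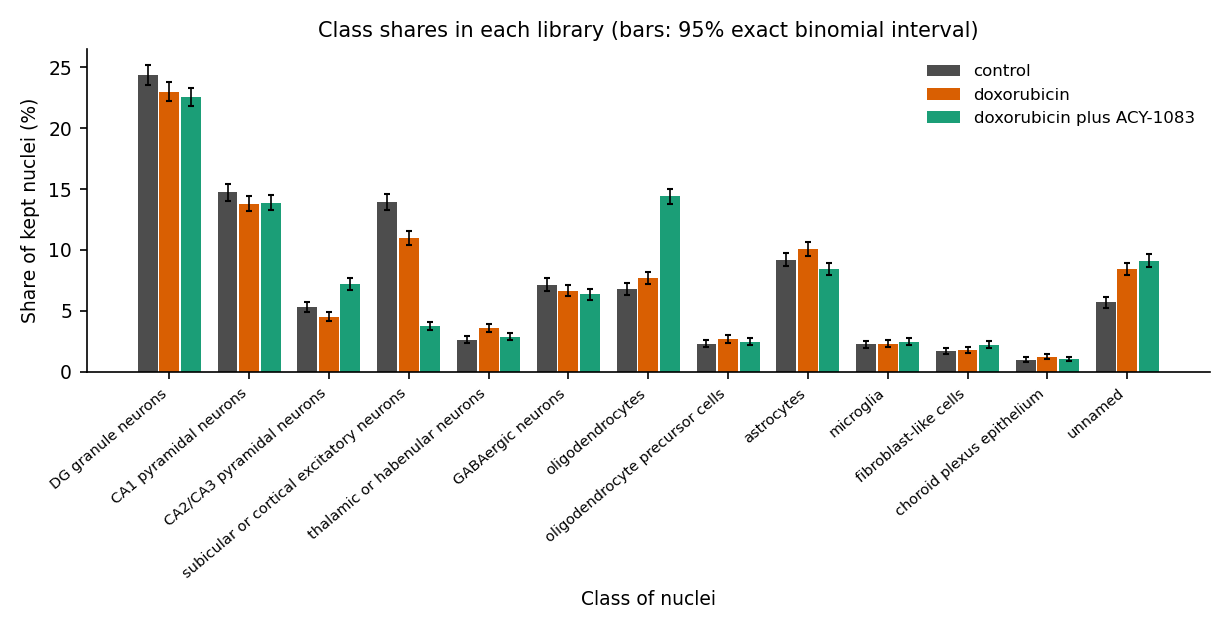
Share of kept nuclei (percent) in each cell class for the control, doxorubicin and doxorubicin plus ACY-1083 libraries, with bars for exact 95% intervals of counting error. Oligodendrocytes were 6.79%, 7.71% and 14.4%, and subicular or cortical excitatory neurons, whose share depended on cluster naming, 13.9%, 10.997% and 3.74%.

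Genes of oxidative phosphorylation were higher in the doxorubicin library than in control in each of the 12 classes, with a list median log2 ratio from 0.16 in astrocytes to 0.52 in oligodendrocytes. In oligodendrocytes 70 of 74 members were higher, led by the complex I subunits Ndufa5 (2.25-fold, 1.61 to 3.20) and Ndufb3 (2.04-fold, 1.44 to 2.92). Granule neurons had 70 of 74 members higher and a median of 0.29, with Ndufb4 at 1.60-fold (1.35 to 1.91) and the ATP synthase gene Atp5e at 1.57-fold (1.28 to 1.93). CA1 neurons had a median of 0.24, GABAergic neurons 0.33 and microglia 0.34. Cytosolic ribosomal protein genes were also higher in 12 of 12 classes, by 0.11 in astrocytes to 0.47 in fibroblast-like cells. Rpl38 was 1.48-fold (1.31 to 1.68) and Rpl27 1.504-fold (1.30 to 1.74) in granule neurons, and Rps28 1.71-fold (1.22 to 2.43) in oligodendrocytes. Each of these list medians lay above the range holding 95% of random lists, and the medians over classes were 0.30 and 0.26. The random lists of this comparison were matched on expression alone. Its ratios also fell with intron length in each class, with a Spearman correlation from -0.00694 in CA2/CA3 neurons to -0.305 in oligodendrocytes, and the percentiles leave this trend in. As a description of these libraries, the median of all genes was between -0.08 and -0.01 in each class.

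Mitochondrially encoded genes were higher in doxorubicin in 10 of 12 classes, with a median over classes of 0.24 and 5 classes above the range holding 95% of random lists. In granule neurons their median was 0.33, with mt-Atp6 at 1.33-fold (1.05 to 1.70), and CA2/CA3 neurons were an exception at -0.22. Oxidative stress genes that respond to Nrf2 were higher in 11 of 12 classes (median 0.15) and above that range in 5. The metallothionein gene Mt3 was 1.71-fold (1.42 to 2.07) and the glutathione peroxidase gene Gpx4 1.65-fold (1.246 to 2.21) in oligodendrocytes, where 14 of 16 members were higher. In GABAergic neurons Mt1 was 1.75-fold (1.39 to 2.21), and in granule neurons the peroxiredoxin gene Prdx1 was 1.40-fold (1.16 to 1.71). Choroid plexus genes were higher in 12 of 12 classes (median 0.41), led by the transport protein gene Ttr, which was 2.08-fold (2.02 to 2.15) in granule neurons and 2.24-fold (2.11 to 2.38) in oligodendrocytes but 1.21-fold (1.15 to 1.28) in choroid plexus epithelium itself. Markers of other cell types, which include Ttr, were 1.53-fold to 1.77-fold higher in doxorubicin when summed in the 6 neuron classes. The single markers did not rise together in each class. In granule neurons 11 were higher and 11 lower, in CA2/CA3 neurons 8 and 8, and in subicular or cortical neurons 16 and 4. Neuron markers summed in the 6 other classes were 0.945-fold to 1.11-fold.

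Immediate early genes, which neuronal activity induces, lay under the range holding 95% of random lists in 2 of 12 classes, subicular or cortical neurons and microglia, and below 0 in 8. In subicular or cortical neurons 12 of 15 members were lower (median -0.22, percentile 0.695), with Npas4 at 0.457-fold (0.324 to 0.637) and Junb at 0.694-fold (0.571 to 0.841). In CA1 neurons 13 of 15 were lower (median -0.20, percentile 2.94 of matched random lists), with Egr3 at 0.723-fold (0.558 to 0.936) and Npas4 at 0.726-fold (0.558 to 0.943). Granule neurons had 8 of 9 lower (median -0.17, percentile 11.4), with Ier5 at 0.626-fold (0.457 to 0.854), and in CA2/CA3 neurons Junb was 0.536-fold (0.389 to 0.733). In oligodendrocytes the list was at 0.30. Circadian clock genes lay below 0 in 10 of 12 classes, and under that range in 3. In astrocytes 12 of 16 clock genes were lower (median -0.29, percentile 0.46), with the output regulator Dbp at 0.489-fold (0.378 to 0.633), and the core gene Clock at 1.49-fold (1.05 to 2.14) went the other way.

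Astrocytes also had lower cholesterol synthesis genes in doxorubicin, with 18 of 19 lower and a median of -0.42 (percentile 0.03), and Msmo1 at 0.628-fold (0.515 to 0.767) and Hmgcs1 at 0.659-fold (0.517 to 0.838). The glucocorticoid-induced gene Tsc22d3 was 0.475-fold (0.350 to 0.641) in astrocytes, although the glucocorticoid-induced list had a median of -0.04 over classes. The reactive astrocyte gene Gfap was 0.778-fold (0.658 to 0.920) in astrocytes, where 5 of 6 measured genes of that list were lower, and 14 of 16 homeostatic astrocyte genes were lower (median -0.20, percentile 1.67). Over classes, homeostatic astrocyte genes lay above 0 in 10 of 12 and above the range holding 95% of random lists in 6: choroid plexus epithelium (0.48), CA2/CA3 neurons (0.36), fibroblast-like cells (0.32), GABAergic neurons (0.31), CA1 neurons (0.08) and granule neurons (0.06). Free astrocyte RNA is not separated from expression in these classes. In oligodendrocytes 18 of 19 myelin genes were lower (median -0.17, percentile 5.73), with Ugt8a at 0.731-fold (0.584 to 0.915) and Mbp at 0.788-fold (0.751 to 0.828), while in GABAergic neurons the myelin list was at 0.34. In microglia the homeostatic list was at -0.06 and the activated list at -0.26 (percentile 10.2), although Apoe, a member of the activated list, was 1.35-fold. Over classes the activated list went the other way, above 0 in 10 of 12 (median 0.18) and above the range holding 95% of random lists in 3.

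Targets of p53, which DNA damage induces, lay below 0 in 11 of 12 classes (median -0.14), and none of the 12 medians was outside the range holding 95% of random lists. In granule neurons Rrm2b was 0.674-fold (0.494 to 0.916) and the p53 ligase gene Mdm2 0.756-fold (0.633 to 0.901), and in CA1 neurons the apoptosis gene Bax was 0.719-fold (0.577 to 0.894). Topoisomerase and DNA repair genes lay below 0 in 11 of 12 classes (median -0.10) but under that range in 1, with Top1 at 0.765-fold (0.616 to 0.9498) in microglia. Histone deacetylases lay below 0 in 10 of 12 classes (median -0.08) and outside that range in 0, with the median of all genes itself below 0 in each class, and Hdac3 at 0.618-fold (0.502 to 0.759) in granule neurons. Senescence and secretory genes were measured in 3 classes (median 0.74) and were at -0.22 in the whole library. Neurogenesis genes were at 0.03 over classes and at -0.33 in CA1 neurons, where Sox11 was 0.670-fold (0.513 to 0.873). Synaptic genes had medians over classes near 0, at -0.03 for presynaptic genes, -0.02 for glutamatergic postsynaptic genes and -0.04 for GABA receptor genes, all of which lay above 0 with TMM scaling. Presynaptic genes lay above the range holding 95% of random lists in 2 classes, and glutamatergic genes above it in 1 and under it in 1. Astrocytes had glutamatergic genes at 0.24, with Gria3 at 1.79-fold, and fibroblast-like cells had them at -0.46. Long nuclear RNAs were at -0.01 over classes (above 0 with TMM scaling) and at 0.67 in astrocytes, where Snhg11 was 1.69-fold (1.58 to 1.81). Medians over classes were near 0 for other lists and crossed it under 1 or more alternatives for most of them, at 0.02 for glycolysis, 0.00 for mitochondrial dynamics and transport, 0.03 for tubulin and microtubule genes, 0.03 for heat shock chaperones, 0.00 for the unfolded protein response, 0.00 for interferon genes and -0.01 for autophagy and lysosome genes. Of these, tubulin and microtubule genes lay above the range holding 95% of random lists in 3 classes, glycolysis in 2, and chaperones and interferon genes in 1 each. Interferon genes lay under it in 1. The dissection lists for thalamus and cortex were at 0.17 and -0.10, and in the whole libraries at 0.08 and -0.12.

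**Figure D2:**
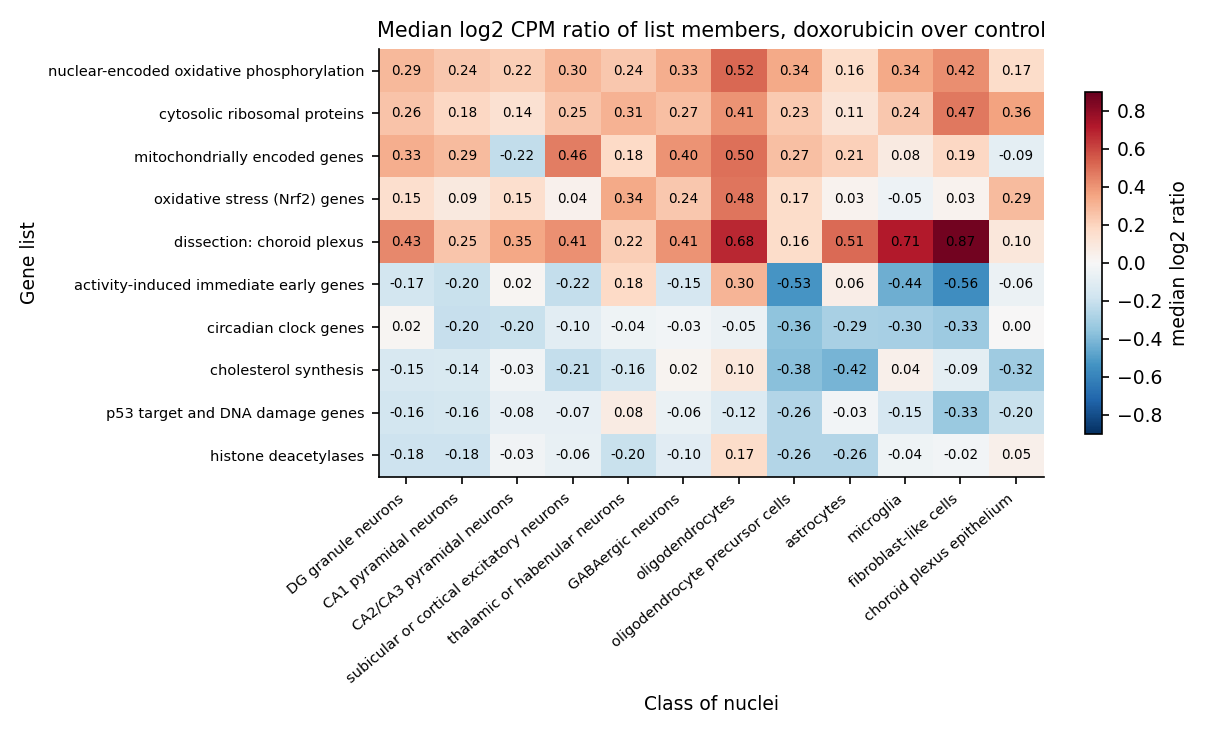
Median log2 CPM ratio of doxorubicin to control for gene lists (rows) in the 12 cell classes (columns), as a colour scale. Oxidative phosphorylation and cytosolic ribosomal protein genes lie above 0 in 12 of 12 classes and p53 targets below 0 in 11 of 12.

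Single genes with the leading ratios between doxorubicin and control differed from class to class. Astrocytes had the copine gene Cpne7 at 3.25-fold (2.31 to 4.67) and the adhesion gene Opcml at 2.22-fold (1.76 to 2.81) higher. Thalamic or habenular neurons had Dbi, which encodes an acyl-CoA binding protein, at 2.78-fold (1.77 to 4.53), and the contactin gene Cntn5 at 0.512-fold (0.393 to 0.666). In granule neurons the secreted peptide gene Ecrg4 was 2.08-fold (1.57 to 2.79) and the peptide transporter gene Slc15a2 1.77-fold (1.46 to 2.17), while the histone gene Hist1h4i had 18.1 CPM against 36.2 CPM in control and Larp1b was 0.543-fold (0.405 to 0.723). CA1 neurons had the mitochondrial import gene Timm8b at 1.74-fold (1.37 to 2.24) and Dbi at 1.56-fold higher, and Man2b1 at 0.615-fold and Ppargc1a, a coactivator of mitochondrial biogenesis, at 0.633-fold (0.518 to 0.771). CA2/CA3 neurons had Ndufc2 at 2.01-fold (1.44 to 2.85) and Chchd2 at 1.73-fold. Subicular or cortical neurons had Dbi at 1.77-fold and the actin-binding peptide gene Tmsb4x at 1.51-fold (1.39 to 1.64).

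GABAergic neurons had the protease gene Ide at 1.95-fold (1.46 to 2.64) and Ndufa4 at 1.75-fold (1.46 to 2.11) higher, and Col19a1 at 0.693-fold. Oligodendrocytes had Cox6c at 1.86-fold (1.51 to 2.30) and the calmodulin gene Calm2 at 1.83-fold (1.58 to 2.12) higher, and Tulp4 at 0.595-fold (0.522 to 0.678) and the histone methyltransferase gene Kmt2a at 0.608-fold. Oligodendrocyte precursor cells had Tmsb4x at 1.65-fold (1.33 to 2.04) and Tial1 at 0.587-fold. Microglia had Cpne7 at 2.28-fold (1.76 to 2.97) and Khdrbs3 at 1.97-fold (1.37 to 2.85), fibroblast-like cells had Sh3pxd2a at 2.18-fold, and choroid plexus epithelium had the glutamate receptor gene Gria2 at 1.65-fold (1.30 to 2.11). Cpne7 was also a leading gene of an unnamed neuron cluster, so free RNA from it is not separated from expression in glia. Free RNA was not separated for the other named genes either. In granule neurons, summed markers of other cell types were 1.53-fold, though 11 single markers were higher and 11 lower. The median absolute log2 ratio was 0.17 over classes, beside 0.10 from counting noise and 0.19 between random splits of the control nuclei, which hold fewer nuclei each. In granule neurons it was 0.11, beside 0.05 from counting noise and 0.08 between splits.

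Between doxorubicin plus ACY-1083 and doxorubicin, the ratio of a gene followed the length of its introns. Genes without introns had a median log2 CPM ratio of -1.50, and genes with over 300 kb of intron 2.39. Long genes led the highest ratios: Ctnna3, a catenin gene with 1566343 bp of intron, was 1568-fold (612 to 5756) higher in subicular or cortical neurons, Nkain2 95.6-fold (75.6 to 123) in oligodendrocytes, Hs6st3 148-fold (91.2 to 259) in CA2/CA3 neurons and Wdr17 348-fold (245 to 512) in astrocytes. In CA1 neurons Ctnna3 was 1430.1-fold (257 to 56499) from 1 UMI in doxorubicin. The antisense gene Nrg3os was 553-fold (254 to 1508.5) in granule neurons and at least 99.9-fold in microglia, and Plxna4os3 at least 254-fold in granule neurons, with strand handling not given in the sources used here. The lowest included genes with little intron, such as Apoe at 0.245-fold (0.234 to 0.256) in granule neurons, Malat1 at 0.290-fold (0.289 to 0.291) in CA1 neurons and Cst3 at 0.256-fold in GABAergic neurons, and also Ahi1, with 120843 bp of intron, at 0.291-fold (0.255 to 0.331) in oligodendrocytes. Genes with over 300 kb of intron took 31.0% of the UMIs of doxorubicin plus ACY-1083, against 6.45% in doxorubicin and 6.85% in control. UMIs per nucleus of genes without introns, most of them of Malat1, were 416, 450 and 430 in control, doxorubicin and doxorubicin plus ACY-1083. Across 10601 genes, which are not independent replicates, the Spearman correlation of the ratio with intron length was 0.765, and -0.131 for doxorubicin against control; over classes it was 0.781 to 0.880, and -0.305 to -0.00694.

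**Figure D3:**
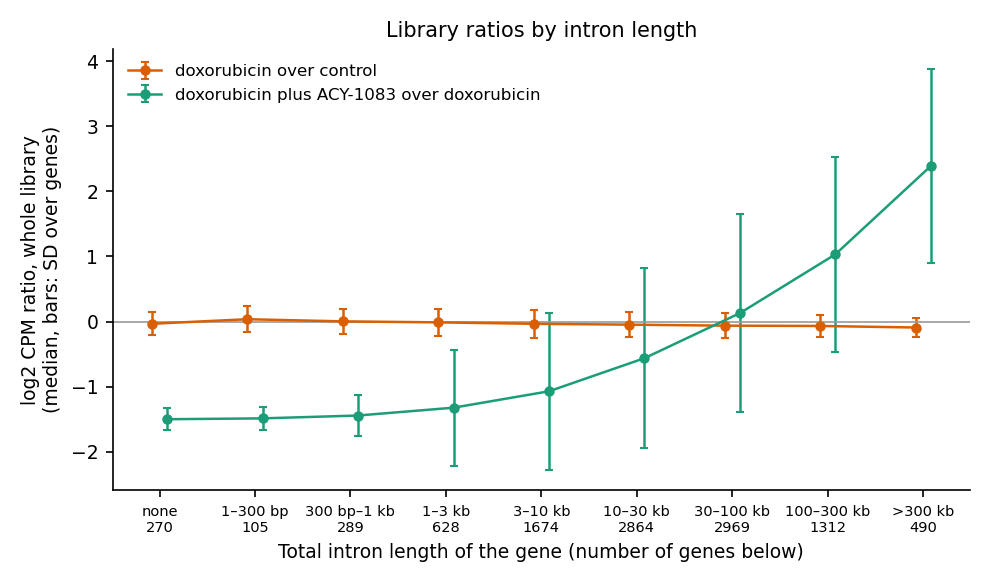
Median log2 CPM ratio over genes in bins of summed intron length, for doxorubicin against control and for doxorubicin plus ACY-1083 against doxorubicin, whole libraries. The latter goes from -1.50 in genes without introns to 2.39 in genes with over 300 kb, and the former stays between -0.09 and 0.04.

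The gene list medians of doxorubicin plus ACY-1083 against doxorubicin covered a wider range, which was not separated from intron length. Cytosolic ribosomal proteins were at -1.29, oxidative phosphorylation genes at -1.11, mitochondrially encoded genes at -1.44 and long nuclear RNAs at -1.54 over classes, while GABA receptor genes were at 0.90 and glutamatergic postsynaptic genes at 0.76 (0.15 and -0.22 relative to lists matched on intron length). The median absolute log2 ratio was 0.99 over classes, beside 0.08 from counting noise and 0.15 between splits of the doxorubicin nuclei. Far below the median of genes without introns, the transcription factor gene Pou3f1, itself without introns, was 0.00926-fold (0.000232 to 0.0526) in subicular or cortical neurons, from 112 UMIs in doxorubicin to 1 UMI. Robo3, an axon guidance gene, was 0.0159-fold (0.00324 to 0.0471) there, and these neurons lay in different clusters in these libraries, with clusters 28 and 32 left out.

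Among short-intron genes, centred on their class median, ratios of doxorubicin plus ACY-1083 to doxorubicin were small. In astrocytes the Notch target Hes5 was 1.26-fold (1.11 to 1.43), after 0.599-fold in doxorubicin against control, and Id1 was 0.608-fold (0.446 to 0.816) and the progenitor factor gene Sox2 0.742-fold (0.597 to 0.916). In CA1 neurons the transcription factor gene Pou3f3 was 1.31-fold (1.13 to 1.52), after 0.848-fold in doxorubicin against control. Both ratios of Hes5 and of Pou3f3 share the doxorubicin library. With that library not split, counting noise alone gave a correlation of -0.586 across short-intron genes. In granule neurons Zfas1 was 1.59-fold (1.29 to 1.95), Hist3h2a 1.42-fold (1.19 to 1.69) and Hist1h1c 0.711-fold (0.561 to 0.897). In oligodendrocytes the dynein light chain gene Dynll1 was 1.21-fold (1.02 to 1.43) and the creatine kinase gene Ckb 1.14-fold (1.02 to 1.27), while the nuclear RNAs Kcnq1ot1 and Neat1 were 0.639-fold (0.563 to 0.726) and 0.740-fold (0.705 to 0.777). With at least 600 genes per nucleus, the log2 ratios in oligodendrocytes, not centred, went from -1.46 to 0.02 for Neat1 and from -0.84 to 0.06 for Ckb. In microglia Kcnq1ot1 was 0.627-fold (0.560 to 0.701). The median absolute log2 ratio of short-intron genes was 0.13 over classes, beside 0.07 from counting noise and 0.12 between splits, and 0.15 in doxorubicin against control.

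Several genes with a higher level in doxorubicin than in control had a lower CPM in doxorubicin plus ACY-1083 than in doxorubicin by the rule for opposite genes. Ecrg4 in granule neurons was 0.307-fold, Dbi in thalamic or habenular neurons 0.333-fold, Calm2 and Cox6c in oligodendrocytes 0.545-fold and 0.544-fold, Cpne7 and Chrd in astrocytes 0.172-fold and 0.197-fold, and Cpne7 in microglia 0.220-fold. Cntn5 in thalamic or habenular neurons, lower in doxorubicin, was 8.55-fold. The rule was met by 6 genes in astrocytes, 2 each in oligodendrocytes and thalamic or habenular neurons, 1 each in granule neurons and microglia, and 0 in the other 7 classes. Genes without introns had a median log2 ratio of -1.50 in the same comparison, so these opposite directions were not separated from the trend with intron length. The unnamed neuron cluster with Cpne7 among its leading genes held 490 nuclei in doxorubicin and 8 in doxorubicin plus ACY-1083. Free RNA from that cluster was therefore not separated from expression of Cpne7 in glia.

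Across genes, the ratios of doxorubicin to control and of doxorubicin plus ACY-1083 to doxorubicin were close to uncorrelated when the shared doxorubicin library was split, with a median Pearson r over classes of -0.0943 (-0.197 to 0.0476) and a covariance of -0.0446. The latter ratios followed intron length, with a Spearman correlation of 0.781 to 0.880 over classes. The r over all genes therefore cannot show whether ACY-1083 reversed differences seen with doxorubicin. Not split, r was -0.210, beside -0.558 from simulated counting noise alone, and the covariance was -0.0870, beside -0.0116. For doxorubicin and doxorubicin plus ACY-1083, each against a different 0.5 of the control nuclei, r was -0.106 and the covariance -0.0681. Not split, r was -0.00977, beside 0.656 from noise, and the covariance -0.00230, beside 0.0174. Short-intron genes, 23 to 60 per class, gave an r of 0.0548 (-0.214 to 0.237) for the opposite direction when split. For the same direction it was 0.161 (-0.00437 to 0.563). Not split, those were -0.193, beside -0.586 from noise, and 0.588, beside 0.663. The covariances not split were -0.00889, beside -0.0093 from noise, and 0.0388, beside 0.0130.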

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

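The tests of free RNA and of depth at 500 UMIs were chosen only after the result was seen, and those of depth at 1000 UMIs and of doublets were written before. An unnamed cluster whose leading genes were mitochondrially encoded genes, Ttr and Fth1 was outside the compared classes and had a larger share in both treated libraries than in control. It held 4.04% (3.70 to 4.41) of the doxorubicin nuclei and 2.92% (2.62 to 3.24) of the doxorubicin plus ACY-1083 nuclei, against 1.48% (1.253 to 1.73) in control. Its median UMIs were 1031, 1023 and 768.5 in control, doxorubicin and doxorubicin plus ACY-1083, and Ttr in it had 4116, 8796 and 5374 CPM. Genes of red blood cells were outside the comparisons too, and their sum was above the control level of 21.1 CPM (19.0 to 23.3) in both other libraries. It was 31.7 CPM (29.3 to 34.2) in doxorubicin, where each of the 5 genes was higher (median log2 ratio 0.41), led in UMIs by Hbb-bs with 292 against 149 in control. It was 40.7 CPM (39.1 to 42.4) in doxorubicin plus ACY-1083, where 1846 of 2375 UMIs were of Alas2, a gene with 20861 bp of intron. The 4 hemoglobin genes alone were at 9.06 CPM (8.31 to 9.87) there. That was below 19.05 CPM (17.1 to 21.2) in control and 29.45 CPM (27.2 to 31.9) in doxorubicin, so the higher CPM sum was of Alas2. CPM of doxorubicin plus ACY-1083 cannot be set directly beside the others. Per 1000 nuclei, hemoglobin UMIs were 33.0, 51.5 and 45.1 in control, doxorubicin and doxorubicin plus ACY-1083, which is above control in both.

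Oxidative phosphorylation and ribosomal protein genes were higher in doxorubicin than in control in 12 of 12 classes, with an oxidative phosphorylation median of 0.30. Median UMIs of kept nuclei were 1467 in control and 1478 in doxorubicin, so these libraries differed little in depth. In the 8 classes that kept enough nuclei when each was thinned to 1000 UMIs, the median was 0.29 (0.2873), beside 0.27 (0.2666) not thinned. Oligodendrocytes, their precursor cells, fibroblast-like cells and choroid plexus epithelium did not keep enough. For these 4, each nucleus was thinned to 500 UMIs, the lowest deposited, with the main classes kept. Their median was 0.46 (0.4596), beside 0.38 (0.3771) not thinned. Thinning keeps the expected share of each gene and changes only which nuclei count and their weight. The thinned medians therefore cannot decide whether depth is a cause. Doublets left in the doxorubicin library were argued against by the median with marked doublets kept, 0.29 (0.2889). More free or cytoplasmic RNA in the doxorubicin droplets stays open and cannot be told apart from the treatment. Markers of other cell types had a median over classes of 0.04 (0.03844), with 0.14 in neurons, so free RNA may account for part of the neurons' difference. In the other cells only neuron markers were used, at 0.00, beside oxidative phosphorylation genes at 0.34. Free RNA of glia or choroid plexus was not covered there, and choroid plexus genes were higher in 12 of 12 classes. RNA from each nucleus's own cytoplasm was not separated. An effect of doxorubicin on these genes is the biological explanation, and it was not tested.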

How the results depend on the processing

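The alternatives with short-intron genes, a floor of 150 short-intron UMIs, deep clusters put back and lists matched on intron length were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and results come from no test. A filter of 200 genes removed no nucleus and tests nothing. Thinning is part of the rule for named genes in the 8 classes it keeps, and putting deep clusters back moves oligodendrocytes alone, so these are left out of the counts for genes they fix. For named genes, 319 of 319 values under the other alternatives kept their direction in doxorubicin against control, and 303 lay within the counting interval. In doxorubicin plus ACY-1083 against doxorubicin 511 of 513 did, and 389 lay within it. The exceptions were Ckb (0.06 against -0.84) and Neat1 (0.02 against -1.46) in oligodendrocytes with at least 600 genes per nucleus. Named genes were picked by size from the same counts, and the alternatives reuse most of the same nuclei. A kept direction was therefore likely in advance and does not show what another library would give. Of list medians, 293 of 349 and 333 of 349 kept their direction. Over alternatives the median over classes in doxorubicin against control was 0.29 to 0.33 for oxidative phosphorylation, 0.24 to 0.30 for ribosomal proteins, 0.21 to 0.34 for mitochondrially encoded genes, -0.24 to -0.09 for immediate early genes and -0.24 to -0.10 for clock genes. These medians did not rest on the same classes: 12 were covered in the main values, but 8 thinned, 9 with at least 600 genes or own clustering, 10 at resolution 0.5, 11 with the UMI floor and, for list members of at least 50 CPM, 5 for mitochondrially encoded and 4 for immediate early genes. The number of nuclei was 26791 to 35317.

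Except where a cause is given, that of the following moves was not tested. The composition distance of doxorubicin to control was 4.79 at resolution 0.5 and 4.11 with at least 600 genes. That of doxorubicin plus ACY-1083 to doxorubicin was 27.7 at resolution 0.5, 14.2 with doublets kept, 23.1 with each library clustered on its own, 20.8 with thinned nuclei and 20.1 with at least 600 genes. At resolution 0.5, CA1 and CA2/CA3 clusters were unnamed in control and doxorubicin (26.6% of doxorubicin nuclei were unnamed) but named in doxorubicin plus ACY-1083 (13.4% and 6.93%), and with own clustering the same classes were at 0% in control and doxorubicin but 10.6% and 5.25%, with 26.5% of doxorubicin and 20.8% of doxorubicin plus ACY-1083 nuclei unnamed, so part of these distances came from naming. The expression difference of doxorubicin to control was 0.143 with doublets kept, 0.175 with own clustering, 0.157 thinned, 0.216 at 30 CPM, 0.138 at 300 CPM, 0.158 with the UMI floor, 0.151 in short-intron genes and 0.119 with at least 600 genes. That of doxorubicin plus ACY-1083 to doxorubicin was 0.928 at resolution 0.5, 0.862 with TMM, 0.880 with own clustering, 0.969 thinned, 0.877 at 30 CPM, 1.27 at 300 CPM, 0.933 with nuclei weighted equally, 1.014 with the UMI floor, 0.131 in short-intron genes and 1.012 with at least 600 genes. The correlation for the opposite direction was -0.0471 with doublets kept, -0.0565 thinned, -0.0222 at 30 CPM, -0.141 at 300 CPM, 0.0548 in short-intron genes and -0.0613 with at least 600 genes. That for the same direction was -0.144 at 300 CPM and 0.161 in short-intron genes. CA1 and CA2/CA3 at resolution 0.5 and with own clustering, and thalamic or habenular neurons with own clustering (0% in control), gave no expression values. TMM shifted the median of all genes from -0.24 to 0.20 in doxorubicin plus ACY-1083 against doxorubicin. Depth limits single genes: of simulated genes changed 2-fold, 71.4% to 94.7% had a bound past 1.5, and of those changed 4-fold 100% did.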

Other observations

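The tests in this part, and the comparison with lists matched on intron length, were chosen only after the results were seen. Matching does not remove differences between genes of like intron length. Among genes with 3000 to 10000 bp of intron, log2 ratios of doxorubicin plus ACY-1083 to doxorubicin had a standard deviation of 1.21. That of doxorubicin to control was 0.21, both in whole libraries. The values matched on intron length are therefore not separated from how reads in introns were counted. The ratio of oxidative phosphorylation genes in doxorubicin plus ACY-1083 to control was -0.84 over classes, below 0 in 12 of 12. It was above that of random lists matched on expression and intron length in 12 of 12 classes. The median difference was 0.25 (0.14 to 0.60) on the log2 scale, past the range holding 95% of matched lists in 11. Against doxorubicin the difference from matched lists was -0.05 (-0.15 to 0.24), with microglia highest and CA1 neurons lowest. Ribosomal protein genes were above matched lists by 0.13 relative to control in 12 of 12 classes, past that range in 4, and were at -0.05 relative to doxorubicin, under it in 5. Immediate early genes lay below matched lists in 11 of 12 classes relative to control, under that range in 6 (median -0.52, subicular or cortical neurons -0.74, astrocytes -0.59), and in 11 of 12 relative to doxorubicin, under it in 4 (median -0.31). Clock genes were at -0.19 relative to control (under that range in 3 classes) and -0.06 relative to doxorubicin (in 0). Long nuclear RNAs were below matched lists in 12 of 12 classes in both comparisons (-0.44 and -0.42), under that range in 8 each. Relative to doxorubicin, homeostatic astrocyte genes were at -0.49 and myelin genes at -0.71 over classes, each under that range in 8, although in oligodendrocytes myelin genes were at 0.22, and activated microglia genes in microglia were at 0.50 (percentile 97.9). Relative to control, activated microglia genes were at most at 0.19 in any class and past that range in 0. Microglia of doxorubicin plus ACY-1083 also had 0.542 times the UMIs per nucleus of genes without introns in doxorubicin. Glutamatergic postsynaptic genes were at -0.22 relative to doxorubicin (under that range in 4 classes) and -0.19 relative to control (in 5), and GABA receptor genes at 0.15 and 0.16. Targets of p53 were at 0.07, cholesterol synthesis genes at -0.15, and tubulin and microtubule genes, which include substrates of HDAC6, at -0.02.

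Rare classes with too few nuclei to compare expression were counted. Endothelial cells were 0.367%, 0.593% and 0.716% of the control, doxorubicin and doxorubicin plus ACY-1083 nuclei, and pericytes 0.193%, 0.284% and 0.580%. In the same order these were 38, 71 and 84 endothelial nuclei and 20, 34 and 68 pericyte nuclei. With at least 150 short-intron UMIs per nucleus, endothelial cells were 0.302%, 0.343% and 0.301%, and pericytes 0.184%, 0.269% and 0.532%. The order of the endothelial shares thus depended on the floor. Committed oligodendrocyte precursors were 0.2701%, 0.0668% and 0.171% (28, 8 and 20 nuclei), Cajal-Retzius cells 0.444%, 0.392% and 0.623%, and ependymal cells 0.299%, 0.317% and 0.247%. An unnamed neuron cluster led by Col6a1, Clec18a and Cpne7 held 409 and 490 nuclei of control and doxorubicin and 8 of doxorubicin plus ACY-1083. Going the other way, 3 unnamed clusters, led by Tshz2, Fn1 and Cpa6, held 534, 146 and 37 nuclei of doxorubicin plus ACY-1083 and 0 of the other libraries.

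The difference between doxorubicin plus ACY-1083 and doxorubicin followed intron length. Deeper sequencing was argued against, since genes without introns had 0.956 times the UMIs per nucleus of doxorubicin, while all genes had 2.85 times. Malat1 gave 4475711 of the 5038970 UMIs of genes without introns in doxorubicin plus ACY-1083 and 4887460 of 5386790 in doxorubicin, so 0.956 is largely the ratio of Malat1. The median log2 CPM ratio over 270 genes without introns, -1.50, does not rest on Malat1. Reads in introns counted in the doxorubicin plus ACY-1083 library and not in the others are a candidate explanation that this same ratio of 0.956 goes with, as do a Spearman correlation with intron length above 0.3 in 12 of 12 classes and the different software versions in the matrix headers. Per class the ratio for genes without introns was 0.892 to 1.13 in 9 classes but 0.542 in microglia, 0.700 in subicular or cortical neurons and 0.7435 in oligodendrocyte precursor cells, lower than intron counting alone gives for the same nuclei, and the cause of that was not tested. A higher expression of genes with long introns after ACY-1083, at 13.7 times the UMIs per nucleus, cannot be told apart from it, because the software version differs with the treatment. An effect of ACY-1083 therefore stays open and untested here.

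The oligodendrocyte share was 14.4% in doxorubicin plus ACY-1083 and 7.71% in doxorubicin, a ratio of 1.87 (1.72 to 2.03). Nuclei with less exonic RNA that pass the same UMI floor in the doxorubicin plus ACY-1083 library were argued against as the whole cause. The ratio was 2.13 (1.89 to 2.40) with at least 175 short-intron UMIs per nucleus. Most short-intron UMIs were of Malat1, so exonic RNA at large was not measured by this floor. At 300 such UMIs the shares were 1.58% and 1.32%, and at 400 they were 0.569% and 1.05% (27 and 54 nuclei). The higher share was thus not seen among oligodendrocyte nuclei with the most short-intron UMIs. What was dissected stays open, as does an effect of ACY-1083, and neither was tested.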
